A study of Mus musculus with 12 samples.

How the data were processed

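MicroRNAs (miRNAs) were measured in 12 samples of total RNA from BC3H1 cells, a mouse brain tumour line with muscle-like properties, on 2-colour Exiqon miRCURY LNA arrays (v10.0). Per the labels, each sample was labelled with Hy3 and set against a common pool labelled with Hy5, with no dye swap. The labels describe the pool both as equal parts of the 3 conditions and as a pool of all 9 samples, although the series holds 12 arrays, so the makeup of the pool stays unsettled. The 3 groups have 4 arrays each: rapamycin-sensitive cells with DMSO for 24 h, sensitive cells with 100 nM rapamycin for 24 h, and the resistant line RR1, grown in 1 µM rapamycin for 6 months and kept in the drug. They are written RS_DMSO, RS_Rap and RR_Rap, with the replicate number of the labels. Nothing says that the replicates of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

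The spot intensity values are those of Agilent Feature Extraction 9.5.3.1, per the file headers and the submitters' processing notes: the mean and median pixel of each spot in both channels and the median of its local background, not normalized, from a scan at 5 µm. Per the file headers, the same software also gave processed intensity values after background adjustment and dye normalization, used here only as an alternative. The deposited value table of the series holds log2 values of unstated scale. Set against the scanner values of the same array, its 417 mouse probes followed the raw log2 of Hy3 over Hy5 with r from 0.969 to 0.998 and slopes from 0.963 to 0.999, so its direction is sample over pool. The array medians of that table ran from 0.393 to 0.604, with no centring to be seen, and how it was summarised over spots is not given in the sources used here. No sample column was left unused.

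From the mean signals, background was corrected in limma 3.58.1 (R 4.3.3) with normexp and an offset of 50, ratios were normalized within each array by loess with control spots at weight 0, and the unflagged spots of a probe (4 per probe) were averaged. The offset shrinks log2 changes of dim probes towards 0. A probe had to be well above background in Hy3, by the software's flag, on at least 3 of the 4 arrays of at least 1 group. That flag was set for all 9468 spots on 11 arrays and for 9463 on RR_Rap 2, so this filter removed no probe, and 417 probes named for mouse miRNAs were tested. As a stricter measure of signal, a probe was counted as above the negative controls when its median Hy3 signal exceeded the highest of the 7 negative-control probes on at least 3 arrays of at least 1 group, which 218 of the 417 did. Names are those of the array's annotation in the files. The names miR-298, miR-34c and miR-744 each have 2 probes, which were tested separately. Their calls differed only for miR-744 in the comparison of the resistant line with 24 h rapamycin, with adjusted p of 0.00473 and 0.257. The number of arrays limits the precision of all values.

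Each comparison was a contrast of 1 limma fit (lmFit and eBayes) to all 12 arrays, with Benjamini-Hochberg adjustment over the 417 probes and a threshold of 0.05. Errors beside a log2 change are the standard errors of that fit. A second question was whether fixed lists of miRNAs shifted as a whole. Of 28 lists, 25 had at least 3 tested members and were tested with limma's camera at an inter-gene correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and fry beside it. The lists were miR-17~92, miR-106a~miR-363, miR-106b~miR-25, let-7, miR-29, miR-15/16, miR-143/miR-145, miR-232724, miR-30, miR-199a/miR-214, miR-181, miR-130/miR-301, miR-125, miR-183miR-96miR-182, the Sfmbt2 cluster, the Dlk1-Dio3 region, muscle-enriched, epithelial (miR-200), neuron-enriched, blood-cell, liver and pancreas, pluripotency-linked, p53-induced, mTOR-targeting and stress-linked miRNAs. The endothelial, miR-221/222 and miR-26 lists had fewer than 3 members and were only described. The groups, tests, lists, other settings and the rule for naming miRNAs were chosen before the data were examined. By that rule the text names, per comparison, up to 12 called miRNAs with the highest and 12 with the lowest log2 change whose 4 and 4 arrays do not overlap, the 2 to 4 members with the smallest p of each list described, and in every comparison all members of miR-17~92, miR-106a~miR-363 and the muscle list. The 8 miRNAs called in both comparisons with DMSO were added to it after their values were seen, which brought in miR-320 and miR-706 for the resistant comparisons, the rule having named both for 24 h against DMSO already.

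The similarity of both responses to DMSO was the Pearson r and covariance across probes, set against 1000 simulated draws of unchanged groups that share the controls and against 6 splits of the controls into separate pairs. Single values per array were compared by exact two-sided permutation tests, for which 4 against 4 arrays allow no p below 0.0286. Genomic neighbours came from the mouse gene table of assembly GRCm38.p6, used for names and adjacency alone, in which 366 of the 417 probes (87.8%) matched a locus by name.

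The steps were tested on simulated data, with each probe's spread taken from its processed ratios. That spread was added before the offset, which shrinks it again, so recovery may be better than in the real data. Both channels were given the same level above background, with no bias by intensity, no unlike array and no flagged spots. The simulation therefore does not test how the steps deal with these. In the comparison of the resistant line with DMSO, over 417 probes, 60.0% of 40 probes changed 1.2-fold, 97.5% of 40 changed 1.5-fold and 100% of 40 changed 2-fold were recovered, with median estimates of 0.21, 0.43 and 0.78 on the log2 scale, and 5 of 288 unchanged probes were called. In the comparison of 24 h rapamycin with DMSO, where nothing was simulated to change, 0 probes were called.

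Other settings tried were another normexp offset (10), no background subtraction, median pixels, median centring without loess, an added Aquantile step, the Hy3 channel alone with quantile normalization, the processed signals, the value table, no filter or a filter over all 12 arrays, probes of any species, a 1.5-fold minimum, only the groups compared, array weights, the replicate number as a block, each array left out in turn, an ordinary unmoderated equal-variance test and the estimated correlation. A filter on the negative controls and centring on the spike-in controls were added after seeing the data. That centring used the median log2 ratio of 4 bright spike-in controls, where the array has 10 spike-in probes. Files gave 12 slides of 1 array each and 1 scan day. Arrays were scanned group after group, RS_Rap first, then RS_DMSO, then RR_Rap, so scan order and group cannot be told apart. Left out of the comparisons were the 1595 probes not designed for mouse, 109 obsolete probes, 77 proprietary miRPlus probes, 14 probes of other names, 12 small-RNA probes and all control probes.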

Results

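The data are ratios of each sample's Hy3 signal to the Hy5 signal of a common pool, on 12 arrays of BC3H1 cells, with 4 arrays each of sensitive cells in DMSO, sensitive cells after 24 h of 100 nM rapamycin, and resistant RR1 cells kept in rapamycin. Rapamycin blocks the kinase complex mTORC1. Over all spots, median Hy3 signals ran from 107 to 144 per array and median Hy5 signals from 70.7 to 100. Median local backgrounds ran from 44 to 57 in Hy3 and from 77 to 105 in Hy5. On each of the 12 arrays the median Hy5 signal lay below the median Hy5 local background. Both filters on signal used Hy3 alone, so the pool signal under a ratio can be near background. Between 130 and 228 of the 417 mouse probes per array stood above the highest negative control, and over the groups 218 did. RS_DMSO 3 stood apart: its correlations across probes with the other DMSO arrays were 0.574 to 0.709, against 0.828 to 0.874 among those, and it had the lowest array weight, 0.150. Across probes, whose values are not independent replicates, the resistant arrays correlated with the 24 h arrays at -0.172 to 0.0557. These are correlations of ratios to a pool that, by 1 of its descriptions, holds all 3 conditions. They show departures from that mixture and do not measure how alike the whole miRNA profiles are.

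Comparing 24 h of rapamycin with DMSO asks which miRNAs differ after a short exposure of sensitive cells. miR-706, at chromosome 6, position 120034228 to 120034311 of GRCm38.p6, fell most, from a mean log2 ratio of 0.32 ± 0.24 to -0.90 ± 0.09 (SD, n = 4), a change of -1.21 ± 0.10 and 2.32-fold (limma adjusted p = 1.75e-05). miR-146a, a feedback inhibitor of NF-κB signalling, rose 1.66-fold, from -0.04 ± 0.20 to 0.69 ± 0.07 (adjusted p = 0.00247). In all, 14 of 417 miRNAs changed, 7 higher and 7 lower. Over all 417 probes 62 had arrays that did not overlap between the groups, where chance gives 2.86%. The other 6 that rose were miR-291b-5p by 1.56-fold, whose arrays overlapped, miR-689 by 1.31-fold, miR-188-3p by 1.28-fold, miR-125b-5p by 1.21-fold, miR-129-5p by 1.21-fold and miR-26a, a regulator of Ezh2, by 1.18-fold. Log2 changes were -0.55 ± 0.11 for miR-805, -0.45 ± 0.09 for miR-668 of the imprinted Dlk1-Dio3 region, -0.40 ± 0.08 for miR-320, -0.29 ± 0.06 for miR-214, -0.22 ± 0.05 for miR-669b and -0.20 ± 0.05 for miR-17, all lower after 24 h. miR-188-3p and miR-669b lay below the negative controls.

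The directions of 6 of these rested on the scaling. Without loess and in the value table, miR-668 stood at 0.32 and 0.41, miR-320 at 0.23 and 0.30, miR-214 at 0.27 and 0.32, and miR-17 at 0.32 and 0.41. With the sample channel alone miR-188-3p stood at -0.26, miR-669b at 0.10 and miR-17 at 0.0077, with the processed signals miR-188-3p stood at -0.09 and miR-17 at 0.12, and with spike-in centring miR-669b stood at 0.04 and miR-17 at 0.06. The split of 7 higher and 7 lower became 106 and 18 without loess, 43 and 5 with the processed signals, 105 and 6 in the value table and 176 and 2 with spike-in centring, which moved the median change of all miRNAs from -0.02 to 0.24. miR-706 alone kept its call under every setting tried. miR-805 lost it without loess, in the value table, with the processed signals and with the sample channel alone, standing at -0.49 to -0.03, and miR-129-5p without loess, in the value table and with the sample channel alone. With the sample channel alone miR-146a, miR-125b-5p, miR-26a and miR-291b-5p lost their calls. miR-125b-5p also lost its call with the processed signals, and miR-689 in the value table. An offset of 10 ended the calls of miR-17, miR-26a, miR-125b-5p, miR-129-5p and miR-669b. An unmoderated test ended every call but that of miR-706. Only miR-706, miR-146a, miR-689 and miR-188-3p passed with any 1 array left out. The other 10 were lost without RS_DMSO 2 (adjusted p = 0.0507 to 0.0672), 9 of them without RS_Rap 4, 6 each without RS_Rap 1 and RS_Rap 2, 5 without RR_Rap 1, 4 each without RS_DMSO 1, RS_Rap 3 and RR_Rap 4, and 1 without RR_Rap 2, with adjusted p up to 0.107. The count was 4 without RS_DMSO 2, 5 without RS_Rap 4, 8 without RS_Rap 1, 9 without RR_Rap 1, 26 without RS_DMSO 3 and 34 without RS_DMSO 4.

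No fixed list shifted as a whole after 24 h: camera called 0 of 25, with 6 at an unadjusted p under 0.05, and camera with an estimated correlation also called 0. fry called 4 lists as moving 1 way on balance and 5 as changing in either direction. The let-7, miR-232724, miR-30 and miR-183miR-96miR-182 lists shifted up without loess and in the value table, and the Dlk1-Dio3 list shifted down in the value table and with the sample channel alone. Of 9 members of the miR-17~92 polycistron, which drives proliferation and is induced by MYC, miR-17 alone was called (1 adjusted over the list alone), with miR-19b at 0.07 ± 0.06, miR-92a at -0.05 ± 0.08, miR-18a at -0.13 ± 0.08, miR-19a at -0.09 ± 0.08 and miR-20a at -0.09 ± 0.10, the last at 0.42 without loess and 0.51 in the value table. miR-17*, miR-18a* and miR-19a* stood at 0.07, -0.06 and -0.08. In the related miR-106a~miR-363 cluster 0 of 6 passed (0 adjusted over the list alone), with miR-106a at 0.26 ± 0.17, miR-20b at -0.28 ± 0.18, miR-20b* at -0.20 and miR-363 at -0.02. Of the 7 muscle-enriched miRNAs 0 passed (0 adjusted over the list alone): miR-1 stood at 0.38 ± 0.20, miR-206 at 0.34 ± 0.19, miR-133a at -0.03, miR-133b at -0.05, miR-486 at -0.21, miR-499 at -0.09 and miR-208 at -0.24. Only 2 of the 7 lay above the negative controls, so for most a change could have been missed.

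Comparing the resistant line with DMSO asks how cells grown in rapamycin for 6 months and kept in it differ from sensitive cells without drug. miR-19b rose 4.15-fold, from -1.34 ± 0.04 to 0.71 ± 0.06 (SD, n = 4), and miR-17 rose 3.13-fold, from -1.10 ± 0.03 to 0.54 ± 0.04 (limma adjusted p = 4.94e-11 for both). Of 9 members of miR-17~92, 7 rose and 0 fell (7 adjusted over the list alone), and the list shifted up (camera adjusted p = 3.88e-08, and adjusted p = 0.0950 with an estimated correlation). On chromosome 14 miR-17 starts at 115043671 and miR-19b ends at 115044391. miR-18a and miR-92a matched no locus by name, so these positions do not give the span of all members. miR-20a rose 2.84-fold, miR-18a 2.36-fold, miR-19a 1.96-fold, miR-92a 1.57-fold and miR-17* 1.45-fold, while miR-18a* and miR-19a*, both below the negative controls, stood at 0.03 and -0.01. Of the 6 members of the miR-106a~miR-363 cluster on chromosome X, 4 rose (5 adjusted over the list alone, camera adjusted p = 0.00998, and adjusted p = 0.0950 with an estimated correlation). They included miR-106a by 2.87-fold and miR-20b by 1.64-fold, whose arrays overlapped and whose call was lost without loess, in the value table and with an unmoderated test, next to miR-19b and miR-92a, which that list shares with miR-17~92. miR-20b* and miR-363, below the negative controls, stood at -0.21 and 0.03. In the miR-106b~miR-25 cluster, which lies in an intron of Mcm7 on chromosome 5, 4 of 5 rose (5 adjusted over the list alone, camera adjusted p = 0.00998, and adjusted p = 0.0950 with an estimated correlation). There miR-93 rose 2.71-fold, miR-106b 2.48-fold and miR-25 1.51-fold.

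**Figure D1:**
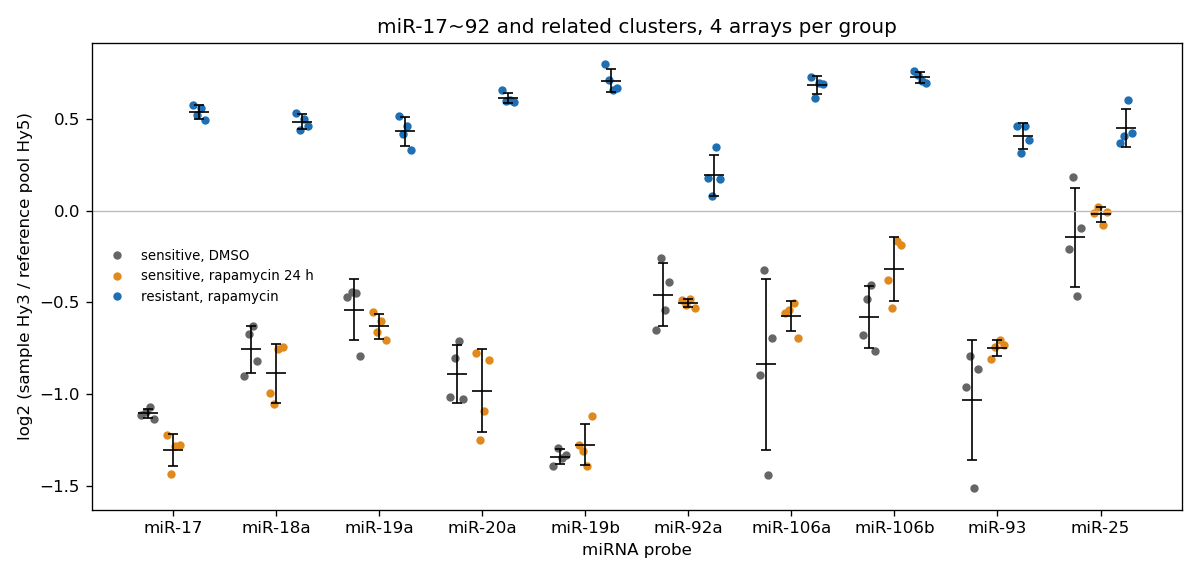
Log2 ratio of sample to reference pool for 10 miRNAs of the miR-17~92, miR-106a~miR-363 and miR-106b~miR-25 clusters, with 1 point per array, bars at the mean ± SD of 4 arrays, and 3 groups. The 4 resistant arrays lie at 0.66 to 0.80 for miR-19b, against -1.39 to -1.29 in DMSO and -1.39 to -1.12 after 24 h of rapamycin.

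miR-143, enriched in smooth muscle and at chromosome 18, position 61649196 to 61649258, fell 4.05-fold in the resistant line, from 0.61 ± 0.14 to -1.40 ± 0.20 (SD, n = 4, limma adjusted p = 4.55e-07). miR-21, raised in many tumours, fell 3.52-fold, from 0.61 ± 0.11 to -1.21 ± 0.11 (adjusted p = 8.68e-10). miR-222 and miR-221, neighbours on chromosome X that target the cell-cycle inhibitor p27, fell 3.40-fold and 1.51-fold, so that both of the 2 members of their list fell (2 adjusted over the list alone). Of 6 members of the miR-29 family, which targets collagen genes, 4 fell (4 adjusted over the list alone, camera adjusted p = 0.0213, and adjusted p = 0.102 with an estimated correlation). miR-29a fell 2.81-fold and miR-29b 1.48-fold. Of the 3 miR-143/miR-145 members 2 fell, miR-143 and miR-145, the latter by 1.15-fold (2 adjusted over the list alone, camera adjusted p = 0.0254, and adjusted p = 0.289 with an estimated correlation). miR-22 fell 2.82-fold, miR-667 2.76-fold, miR-675-5p, made from the imprinted H19 RNA, 2.67-fold and miR-690 2.06-fold. miR-146a, which rose after 24 h of rapamycin, fell 1.66-fold here, from -0.04 ± 0.20 to -0.77 ± 0.16. Of 5 members of the miR-199a/miR-214 list 3 fell (3 adjusted over the list alone, camera adjusted p = 0.0290, and adjusted p = 0.173 with an estimated correlation). Among them miR-214 fell 1.63-fold and miR-199a-3p/miR-199b 1.40-fold. Without RS_DMSO 2 and without RS_DMSO 4 the shift of that list had an adjusted p of 0.0514 and 0.06.

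**Figure D2:**
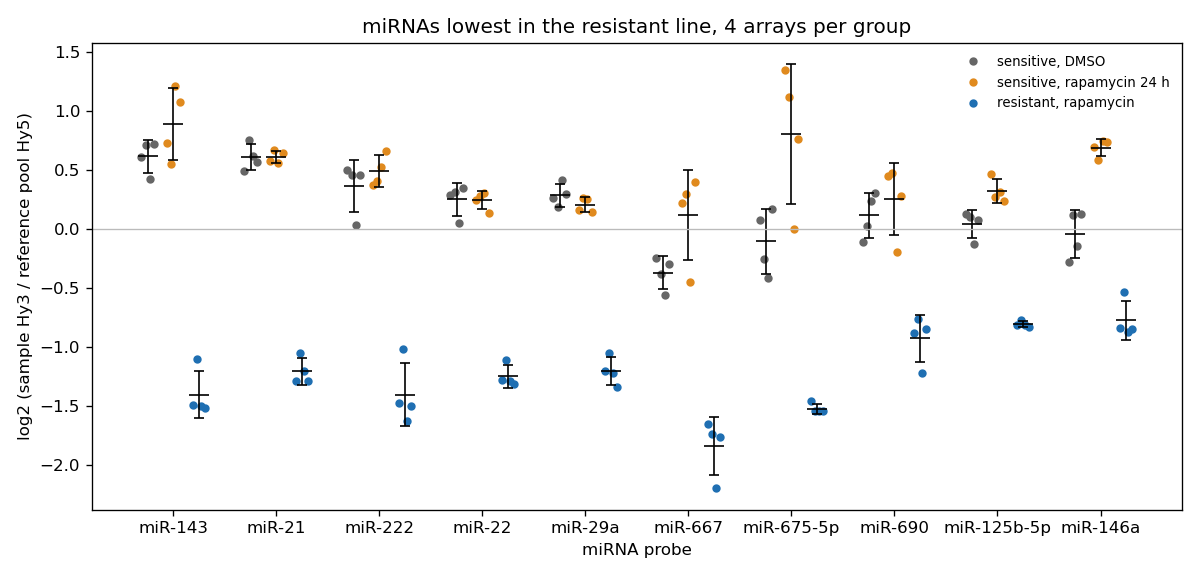
Log2 ratio of sample to reference pool for 10 miRNAs lower in the resistant line than in DMSO, with 1 point per array, bars at the mean ± SD of 4 arrays, and 3 groups. The resistant arrays lie at -1.52 to -1.10 for miR-143, against 0.42 to 0.72 in DMSO and 0.55 to 1.21 after 24 h of rapamycin.

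Other lists also moved in the resistant line. In the miR-183miR-96miR-182 polycistron, known from sensory organs, 3 of 4 rose (3 adjusted over the list alone, camera adjusted p = 0.00998, and adjusted p = 0.173 with an estimated correlation). miR-96 rose 1.89-fold, miR-182 1.71-fold and miR-183 1.62-fold. In the miR-130/miR-301 family 3 of 4 rose (3 adjusted over the list alone, camera adjusted p = 0.0251, and adjusted p = 0.103 with an estimated correlation). miR-130b rose 1.80-fold, miR-301a 1.53-fold and miR-130a 1.25-fold. The call of miR-301a was lost without loess and in the value table. In the miR-30 family 4 of 7 rose (4 adjusted over the list alone, camera adjusted p = 0.0254, and adjusted p = 0.253 with an estimated correlation). miR-30e rose 1.78-fold and miR-30c 1.43-fold. Without RR_Rap 2 the adjusted p of the list was 0.0513. Of 4 miR-125 members, miR-125b-5p fell 1.80-fold and miR-125a-5p 1.33-fold (4 adjusted over the list alone), and the list missed the threshold (camera adjusted p = 0.0607). Single miRNAs that rose were miR-805 by 4.88-fold, from -1.43 ± 0.16 to 0.86 ± 0.06, miR-370 by 1.89-fold, a call lost without loess and in the value table, and miR-31 by 1.83-fold. Of the 7 muscle-enriched miRNAs 0 passed (0 adjusted over the list alone): miR-1 stood at -0.30 ± 0.20, miR-206 at -0.28 ± 0.19, miR-486 at -0.27, miR-133b at -0.08, miR-133a at -0.07, miR-499 at 0.00 and miR-208 at 0.17. Again only 2 of the 7 lay above the negative controls.

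In this comparison 97 miRNAs changed, 54 higher and 43 lower, of which 16 changed at least 2-fold and 80 lay above the negative controls. Over all 417 probes 106 had arrays that did not overlap (2.86% by chance). The split was 37 higher and 63 lower without loess, 39 and 16 with the sample channel alone, 79 and 24 with the processed signals, 32 and 44 in the value table and 55 and 24 with spike-in centring. Of the 9 lists, 6 up and 3 down, the 3 miR-17 clusters alone passed with the sample channel, and those with miR-143/miR-145 with the processed signals. Without loess the miR-143/miR-145 and miR-30 lists were lost, in the value table miR-143/miR-145 and miR-199a/miR-214, without background subtraction miR-199a/miR-214, and with an offset of 10 or the negative-control filter miR-30. With the sample channel alone the calls of let-7b, miR-29b, miR-30c, miR-125b-5p, miR-129-5p, miR-130a, miR-145, miR-182, miR-183, miR-199a-3p/miR-199b, miR-320 and miR-494 were lost, with the processed signals those of let-7b, let-7i, miR-29b, miR-125a-5p, miR-129-5p, miR-199a-3p/miR-199b and miR-706, and in the value table those of miR-25 and miR-320. miR-320 was also lost without loess, miR-29b, miR-320 and miR-706 without background subtraction, miR-145 with an offset of 10, and let-7b, miR-145 and miR-320 with spike-in centring. Of 45 called miRNAs named for this comparison 43 passed with any 1 array left out. The naming rule favours large changes and small p, so this share does not hold for all calls. Of all 97 calls, 77 were kept without RS_DMSO 1, RR_Rap 3 or RR_Rap 4, the fewest for any 1 array. miR-145 was lost without RS_DMSO 2, RS_DMSO 4, RR_Rap 1, RR_Rap 3 or RR_Rap 4 (adjusted p = 0.0568 to 0.0742), and miR-320, higher by 1.18-fold, without any array but RS_DMSO 3, RS_Rap 2 or RS_Rap 3 (adjusted p = 0.0572 to 0.133).

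Setting the resistant line against sensitive cells after 24 h compares cells that both had rapamycin in the medium, at doses of 1 µM and 100 nM. miR-805 was 7.16-fold higher, miR-19b 3.96-fold and miR-17 3.59-fold (n = 4, limma adjusted p = 1.22e-09, 6.47e-11 and 2.62e-11), from means of -1.98 ± 0.24, -1.28 ± 0.11 and -1.31 ± 0.09 (SD). miR-675-5p was 5.02-fold lower and miR-143 4.90-fold lower, from 0.89 ± 0.30, and miR-667, of the Dlk1-Dio3 region, was 3.88-fold lower. In miR-17~92, 7 of 9 rose (8 adjusted over the list alone, camera adjusted p = 5.55e-08, and adjusted p = 0.112 with an estimated correlation). miR-20a rose 3.02-fold, miR-18a 2.59-fold, miR-19a 2.09-fold, miR-92a 1.62-fold and miR-17* 1.38-fold. miR-18a* stood at 0.10 and miR-19a* at 0.07. In the miR-106a~miR-363 list 4 of 6 rose (4 adjusted over the list alone, camera adjusted p = 0.00979, and adjusted p = 0.115 with an estimated correlation). miR-106a rose 2.39-fold and miR-20b 2.00-fold. miR-20b* stood at -0.01 and miR-363 at 0.05. In miR-106b~miR-25, 4 of 5 rose (4 adjusted over the list alone, camera adjusted p = 0.0406, and adjusted p = 0.139 with an estimated correlation). miR-93 rose 2.22-fold, miR-106b 2.06-fold and miR-25 1.39-fold.

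Among miRNAs lower in the resistant line than after 24 h, miR-222 was 3.72-fold lower and miR-221 1.66-fold, miR-21 3.52-fold, miR-22 2.81-fold, miR-146a 2.76-fold and miR-690 2.27-fold. All 3 miR-143/miR-145 members fell (3 adjusted over the list alone, camera adjusted p = 0.00979, and adjusted p = 0.221 with an estimated correlation), miR-145 by 1.23-fold. In the miR-29 family 3 of 6 fell (4 adjusted over the list alone, camera adjusted p = 0.0417, and adjusted p = 0.139 with an estimated correlation). miR-29a fell 2.65-fold and miR-29b 1.90-fold. Of 4 miR-125 members 2 fell (2 adjusted over the list alone, camera adjusted p = 0.0494, and adjusted p = 0.139 with an estimated correlation), miR-125b-5p by 2.19-fold and miR-125a-5p by 1.33-fold. In the miR-130/miR-301 family 3 of 4 rose (3 adjusted over the list alone, camera adjusted p = 0.0481, and adjusted p = 0.139 with an estimated correlation), with miR-130b by 1.98-fold. Of 7 muscle-enriched miRNAs, 2 of them above the negative controls, 1 rose and 2 fell (3 adjusted over the list alone). The list had an adjusted p of 0.794. miR-208, below the negative controls, rose 1.33-fold, miR-1 fell 1.60-fold and miR-206 fell 1.53-fold. miR-486 stood at -0.07, miR-133a at -0.04, miR-133b at -0.02 and miR-499 at 0.09.

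In all 120 miRNAs changed between both rapamycin groups, 63 higher and 57 lower in the resistant line, 94 of them above the negative controls. Over all 417 probes 166 had arrays that did not overlap (2.86% by chance). The split was 57 higher and 135 lower without loess, 15 and 121 in the value table and 27 and 122 with spike-in centring, which moved the median change of all miRNAs from 0.03 to -0.19. miR-320 was 1.56-fold higher, but stood at -0.09 without loess and -0.16 in the value table. Of 37 called miRNAs named for this comparison 35 passed with any 1 array left out. Of all 120 calls, 95 were kept without RS_Rap 2, the fewest for any 1 array. miR-1 was lost without RR_Rap 1, RR_Rap 3, RR_Rap 4 or RS_Rap 1 (adjusted p = 0.0510 to 0.0584) and miR-206 without any of these or RS_Rap 2, RS_Rap 3 or RS_Rap 4 (adjusted p = 0.0653 to 0.0835). Of the 7 lists, 4 passed without RS_Rap 4. The miR-29 list was lost without RS_Rap 4 or RR_Rap 3 (adjusted p = 0.0726 and just over 0.05), miR-130/miR-301 without RR_Rap 1, RS_Rap 4 or any 1 DMSO array (adjusted p = 0.0502 to 0.0742), and miR-125 without RR_Rap 1, RR_Rap 2, RS_Rap 2, RS_Rap 4 or any 1 DMSO array (adjusted p = 0.0533 to 0.0726). Without loess the miR-143/miR-145, miR-29, miR-130/miR-301 and miR-106b~miR-25 lists were lost, and in the value table all of these but miR-106b~miR-25. Array weights ended miR-29, miR-130/miR-301 and miR-125, the sample channel alone, an offset of 10 and a fit to the groups compared ended miR-130/miR-301 and miR-125, the replicate block ended miR-125, and the negative-control filter, which left miR-143/miR-145 too small to test, kept miR-17~92 and miR-106a~miR-363 alone. Without loess and in the value table the calls of miR-20b, miR-25, miR-17*, miR-208 and miR-494 were lost, in the value table those of miR-19a and miR-106b too, and with the sample channel alone those of miR-1, miR-7a, miR-206, miR-208, miR-494, miR-17*, miR-29b and miR-125b-5p.

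The changes after 24 h and in the resistant line, both against the same DMSO arrays, had a Pearson r of -0.0233 across 417 miRNAs, which are not independent replicates, where simulated unchanged groups sharing their controls gave a mean of 0.50 (central range 0.377 to 0.608 over 1000 draws). With the DMSO arrays split into separate pairs the mean r over 6 splits was -0.111. The simulation holds no change in any group, whereas 97 miRNAs were called in the resistant line, and such changes also move r. The gap to 0.50 is therefore no evidence of opposed responses, and the sign of r changed with the processing. The covariance was -0.0016, against a simulated mean of 0.0042 and a mean of -0.0090 over the splits. Of the 14 miRNAs called after 24 h, 8 were called in the resistant line too. Both comparisons had miR-706 and miR-214 lower, miR-706 by 2.32-fold after 24 h and 1.47-fold in the resistant line, although miR-214 after 24 h stood at 0.27 without loess. The other 6 went opposite ways: miR-146a, miR-125b-5p and miR-129-5p were higher after 24 h and lower in the resistant line, and miR-805, miR-320 and miR-17 lower after 24 h and higher in the resistant line, except that miR-320 and miR-17 after 24 h stood at 0.23 and 0.32 without loess. Independent random lists of these sizes would share 1.63 miRNAs with the same direction and 1.63 with opposite directions, but these comparisons share their DMSO arrays. The call of miR-805 after 24 h was also lost without loess, where it stood at -0.13, in the value table at -0.03, with the processed signals at -0.36 and with the sample channel alone at -0.49. That of miR-129-5p after 24 h was lost without loess at 0.31, in the value table at 0.35 and with the sample channel alone at 0.27.

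**Figure D3:**
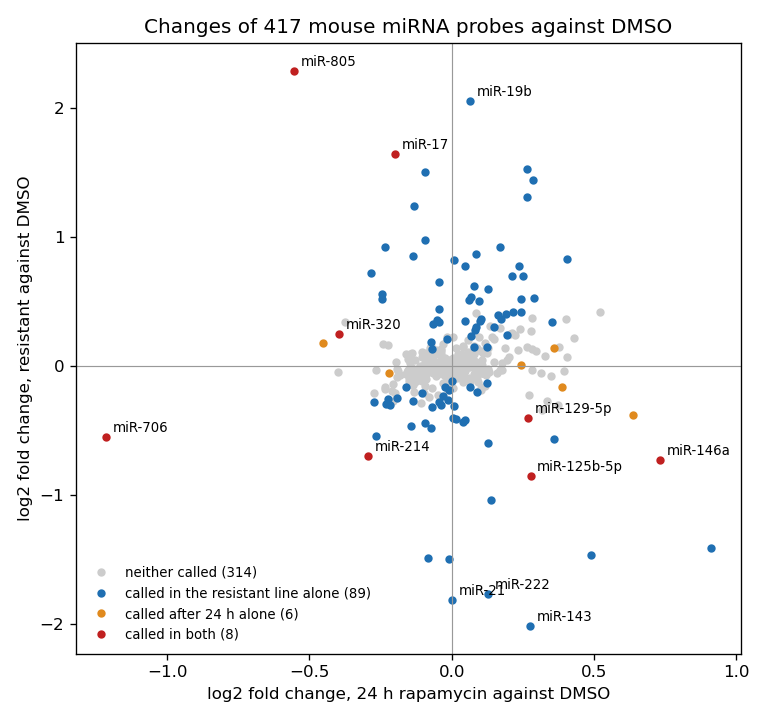
Log2 change against DMSO after 24 h of rapamycin (x axis) and in the resistant line (y axis), with 1 point for each of 417 miRNA probes, coloured by the comparisons in which it was called. Of these, 89 were called in the resistant line alone, 6 after 24 h alone, 8 in both and 314 in neither.

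The 12 probes for small nuclear and nucleolar RNAs, often used as references, had median log2 differences of 0.07 after 24 h (exact permutation p = 0.171), 0.09 in the resistant line against DMSO (exact p = 0.0857) and 0.03 between both rapamycin groups (exact p = 0.343), two-sided, with 0.0286 the smallest p possible. Without background subtraction the value against DMSO in the resistant line was 0.09, at the smallest exact p. With the sample channel alone the resistant line stood at 0.65 against DMSO and 0.63 against 24 h. Without loess and with the processed signals the median after 24 h was 0.23 and 0.24, and that between both rapamycin groups turned to -0.14 and -0.06, none of these passing the exact test. Single probes differed in the resistant line against DMSO (limma, adjusted over the 12). Higher were SNORD2 at 0.99 ± 0.08, SNORD12 at 0.67, SNORD14B at 0.48 and SNORD13 at 0.25. Lower were U6-snRNA-2 at -0.86, U6-snRNA-1 at -0.67, SNORD118 at -0.22 and SNORD6 at -0.14. Against 24 h 7 of the 12 differed in the resistant line, among them U6-snRNA-1 at -1.03, SNORD3@ at -0.97 and U6-snRNA-2 at -0.94 lower and SNORD2 at 0.76 higher, so the median near 0 covers probes that went both ways. After 24 h against DMSO none passed, the lowest adjusted p being 0.0670. The signal of the array's Hy3 control spots was 60678 ± 153 on resistant arrays, 49906 ± 1063 in DMSO and 50307 ± 472 after 24 h (SD, n = 4, exact permutation p = 0.0286 for the resistant line against DMSO). The 4 bright spike-in controls had median log2 ratios of 0.01 ± 0.20 in DMSO, -0.25 ± 0.05 after 24 h and -0.03 ± 0.03 in the resistant line, and the 24 h arrays differed from DMSO by -0.26 (exact permutation p = 0.114). The resistant line differed from 24 h by 0.22, at the smallest exact permutation p of 0.0286, and from DMSO by -0.04 (exact permutation p = 0.771).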

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

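The tests for cross-hybridisation between related probes and for the loess step, and the spike-in centring, were chosen only after the results they bear on were seen.

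The miR-17~92, miR-106a~miR-363 and miR-106b~miR-25 miRNAs were higher in the resistant line. If 1 rising miRNA had spilled onto the probes of its near-identical relatives, members with other sequences would not have risen. The lowest log2 change among miR-18a, miR-19a, miR-19b and miR-92a was 0.65, which argues against this as the whole cause within miR-17~92. Those probes all belong to miR-17~92, so for miR-106b~miR-25 the test cannot decide and cross-hybridisation stays open. The Hy3 control spots were brighter on the resistant arrays. Median centring removes a uniform brightening beforehand, so only a shift that depends on brightness could be tested. Without loess, the 20 probes matched in brightness to each called member had medians of -0.23 to 0.04, with -0.13 in the middle. The 13 called members, picked by their call in this comparison, stood at 0.16 to 1.95, with a median of 0.89. For those members the values argue against a brightness-dependent shift as the whole cause. For miR-106a~miR-363, cross-hybridisation from miR-17~92 stays open, since 0 of miR-363 and miR-20b*, the members that could tell them apart, lay above the negative controls. A change of the resistant line, a difference in drug dose or time and the order of scanning remain possible and cannot be told apart, as all move with the group.

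miR-146a, miR-125b-5p, miR-129-5p, miR-805, miR-320 and miR-17 changed in opposite directions after 24 h and in the resistant line, and the resistant line differed from 24 h by -1.46, -1.13, -0.68, 2.84, 0.64 and 1.84, which follows from how these 6 were chosen and is no separate evidence. Without RS_DMSO 3, 6 of 6 kept opposite signs, which argues against that array as the cause, and with spike-in centring 5 of 6 did, with 4 called in both and miR-17 turned. Without loess 4 of 6 did, with 2 called in both, so the loess step stays open: it may give miR-320 and miR-17 their opposite signs and most of the fall of miR-805 after 24 h, which stood at -0.13 without loess and was not called. miR-129-5p was not called without loess either, but its change after 24 h was no smaller, at 0.31 against 0.27.

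RS_DMSO 3 stood apart from its group. Its mean correlation with its own group was 0.627 and the highest with another group 0.518 (24 h rapamycin), so a wrong label or a mixed sample stays open, with no partner array out of place. Noise near background is argued against as the whole cause, because over the 82 probes above the negative controls on all 12 arrays its mean correlation was still 0.737, against at least 0.924 among the other DMSO arrays. It had 295 spots marked as non-uniform in either channel, against 5 to 135 on the other arrays. No biological explanation was tested.

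Each pair of groups can be divided into 4 and 4 arrays in 35 ways, the real one among them. Only the real division, 1 of 35, reached the 14 miRNAs after 24 h (highest other 1). The same held for the 97 in the resistant line against DMSO (highest other 2) and the 120 against 24 h (highest other 0). It also held for the 9 lists (highest other 2) and the 7 lists (highest other 4), as camera counts them with its preset correlation. These counts argue against a random division of the arrays, at the smallest share that 35 divisions allow. They cannot separate a change of the cells from scan order or anything else that moves with the group. Nor do they bear on single calls. With an estimated correlation camera called 0 lists in both of these comparisons, and the 7 lists became 4, the highest of the other splits, without RS_Rap 4 and with array weights. For the 0 lists after 24 h the count of 35 of 35 (highest other 2) was fixed in advance, as no split can give fewer, and says nothing about chance.

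Single arrays lay far from the rest of their group in 18 of 213 groups of 4 tested, where chance gives 10.65, and 8 of these were in RR_Rap 2. On RR_Rap 2 the log2 ratios were -0.12 for let-7b, -0.46 for miR-129-5p, -1.10 for miR-143, -0.53 for miR-146a, -0.37 for miR-188-3p, -0.22 for miR-199a-3p/miR-199b, 0.22 for miR-206 and -1.11 for miR-22. On other resistant arrays miR-133a stood at -0.21 and miR-363 at 0.27 (both RR_Rap 3) and miR-675-5p at -1.46 (RR_Rap 1). In DMSO they were miR-19a at -0.79 and miR-26a at -0.12 (both RS_DMSO 4) and miR-222 at 0.035 (RS_DMSO 3). After 24 h they were miR-130b at -0.72 and miR-706 at -1.02 (both RS_Rap 1), and miR-20b* at 0.10 and miR-494 at -0.25 (both RS_Rap 2).

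Probes left out of the comparisons also gave signal above the negative controls: 415 of 1595 not designed for mouse, 30 of 77 miRPlus probes and 36 of 109 obsolete probes.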

How the results depend on the processing

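Filtering on the negative controls and centring on the spike-in controls were chosen only after the results were seen. Other alternatives were set beforehand. Where no reason is given, the cause was not tested. Of 30 alternatives for named miRNAs, 3 changed no value (both background filters and the added Aquantile step) and say nothing. Under the other 27, 3315 values kept their side of the threshold, 217 lost the call, 38 gained one and 19 reversed. A change of sign counted as a reversal only where the value was called in the main fit or in the alternative. The 3315 therefore include uncalled values that changed sign, such as miR-18a after 24 h, which ran from -0.18 to 0.33. miR-706 after 24 h kept its call under all 27. In the resistant line against DMSO miR-17, miR-19b, miR-20a, miR-106a, miR-93 and miR-805, which rose, were among those that did. So were miR-143, miR-21, miR-222, miR-22 and miR-29a, which fell.

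Counts are given below in the order 24 h against DMSO, resistant against DMSO, resistant against 24 h, where several stand together. No background subtraction gave 49 after 24 h, a similarity of the responses of 0.062 and a small-RNA difference of 0.095 in the resistant line at the smallest exact p. Without loess there were 124 after 24 h and 192 against 24 h, 4 lists after 24 h and a similarity of -0.16. miR-668 stood at 0.32, miR-320 at 0.23, miR-214 at 0.27, miR-17 at 0.32 and miR-20a at 0.42 after 24 h, and miR-320 at -0.086 against 24 h. The value table gave 111 after 24 h, 5 lists, and 0.41, 0.30, 0.32, 0.41 and 0.51 for those miRNAs, with miR-320 at -0.16 against 24 h. The sample channel alone gave 2, 55 and 54, 1 list after 24 h and 3 in the resistant line, a similarity of 0.15, small-RNA differences of 0.65 and 0.63 in the resistant line, and miR-188-3p at -0.26, miR-669b at 0.10 and miR-17 at 0.0077 after 24 h. The processed signals gave 48 after 24 h, 4 lists in the resistant line, a similarity of 0.28, and miR-188-3p at -0.094 and miR-17 at 0.12. Spike-in centring gave 178 after 24 h, with miR-669b at 0.039 and miR-17 at 0.059. Counting all probes gave 66, 301 and 393, with more probes tested, and a 1.5-fold minimum 3, 35 and 40. Fitting only the groups compared gave 5, 79 and 168, and an unmoderated equal-variance test 1, 69 and 158. Array weights gave 183 against 24 h, 4 lists and a similarity of -0.11. An estimated correlation left 0 lists in both resistant comparisons, and the negative-control filter 2 lists against 24 h.

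Leaving out 1 array gave 4 to 34 after 24 h, 77 to 107 in the resistant line against DMSO and 97 to 145 against 24 h. The lists ran 0 to 0, 8 to 10 and 4 to 7, the similarity from -0.066 to 0.075, and 52 to 61 of the 61 calls with the highest and lowest changes, summed over the comparisons so that a miRNA can count in several, kept direction and side of the threshold. The replicate numbers paired no arrays (r from -0.114 to 0.151). With them as a block the counts were 20, 89 and 113, the lists 0, 9 and 6, and the similarity -0.02. Blocks for slide or scan day were not run, since each slide held 1 array and there was 1 day, and the value table has no small-RNA probes. Of the 417 probes 218 lay above the negative controls. Signal over background limits the rest.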

Other observations

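The fit to the probes left out of the comparisons was chosen only after the data were seen.

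Of the 46 measured miRNAs of the imprinted Dlk1-Dio3 region, members moved both ways. In the resistant line against DMSO 2 rose and 7 fell (9 adjusted over the list alone), with miR-370 up 1.89-fold and miR-494 up 1.47-fold beside miR-667 down 2.76-fold. Against 24 h 4 rose and 9 fell (13 adjusted over the list alone), with miR-370 up 2.22-fold and miR-494 up 1.74-fold, a call lost without loess, where miR-494 stood at 0.05, in the value table at 0.08 and with the sample channel alone. After 24 h only miR-668 passed, lower here but higher without loess and in the value table. Camera called the list in none of the 3 comparisons (adjusted p = 0.903, 0.551 and 0.690). In the let-7 family of 9, linked to differentiation, 1 rose and 3 fell in the resistant line against DMSO (4 adjusted over the list alone, camera adjusted p = 0.733), with let-7i down 1.36-fold and let-7b 1.22-fold. With the processed signals both calls were lost, at -0.21 and -0.06, and let-7b was also lost with the sample channel alone and with spike-in centring. Against 24 h 1 rose and 3 fell (5 adjusted over the list alone, adjusted p = 0.690). After 24 h 0 passed, and the sign of its test turned from lower to higher without loess, with the sample channel alone, with the processed signals and in the value table. Of the 9 stress-linked miRNAs, miR-146a alone passed after 24 h (2 adjusted over the list alone, camera adjusted p = 0.143). In the resistant line against DMSO miR-21 and miR-146a fell while miR-31 and 1 other rose (4 adjusted over the list alone, adjusted p = 0.551), and against 24 h 2 rose and 4 fell (7 adjusted over the list alone, adjusted p = 0.0998).

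Among 14 neuron-enriched miRNAs, miR-129-5p rose after 24 h (3 adjusted over the list alone), 3 fell in the resistant line against DMSO (3 adjusted over the list alone), miR-129-5p by 1.33-fold among them, and 2 rose and 2 fell against 24 h (4 adjusted over the list alone), with miR-7a up 1.64-fold, a call lost with the sample channel alone, and miR-129-5p down 1.60-fold. Camera did not call that list in any comparison (adjusted p = 0.366, 0.548 and 0.958), while fry's test for change in either direction gave an unadjusted p of 0.000503, 5.14e-07 and 1.71e-09. That test called 5, 16 and 18 of the 25 lists after adjustment. Over all 417 probes, 23.3% were called in the resistant line against DMSO and 28.8% against 24 h. The neuron-enriched list lay near these shares, so its small p sets it apart from no other list. Of 7 blood-cell miRNAs 1 rose and 1 fell against 24 h (2 adjusted over the list alone), with 0 called in both other comparisons (2 and 0 adjusted over the list alone). For 5 liver and pancreas, 8 epithelial and 2 endothelial miRNAs limma called 0 in any comparison, with 1 epithelial and 1 endothelial adjusted over the list alone after 24 h. Only 1, 1 and 0 of these lay above the negative controls, so most had too little signal to show a lack of change. Also 0 were called in the miR-15/16 (6 members), miR-232724 (7) and miR-181 (5) lists, against 2 and 1 adjusted over the list alone for the last pair after 24 h. Of these, 5, 6 and 2 members lay above the negative controls. Of 11 pluripotency-linked miRNAs miR-291b-5p rose after 24 h (1 adjusted over the list alone), 1 fell in the resistant line against DMSO (0 adjusted over the list alone), and 2 rose and 1 fell, miR-291b-5p by 2.03-fold, against 24 h (3 adjusted over the list alone). Of 6 mTOR-targeting miRNAs 0 passed after 24 h, miR-199a-3p/miR-199b fell against DMSO (1 adjusted over the list alone) and 2 fell against 24 h (3 adjusted over the list alone). Of 7 p53-induced miRNAs, 2 of which lay above the negative controls, 1 rose in the resistant line against DMSO (0 adjusted over the list alone). In the Sfmbt2 cluster of 7, miR-669b fell after 24 h (1 adjusted over the list alone), though it stood higher with the sample channel alone and with spike-in centring, and 1 rose against 24 h (0 adjusted over the list alone). The single miR-26 probe rose after 24 h, stood at 0.00 against DMSO in the resistant line and fell against 24 h, at -0.24.

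For lists already described, camera missed the threshold against 24 h for miR-30 (4 of 7 rose, 5 adjusted over the list alone, adjusted p = 0.375), miR-183miR-96miR-182 (3 of 4 rose, 4 adjusted over the list alone, adjusted p = 0.0998) and miR-199a/miR-214 (3 of 5 fell, 3 adjusted over the list alone, adjusted p = 0.0998). After 24 h, 3 miR-30 members and 1 miR-183 member passed adjusted over the list alone. Median, mean and test differed in sign after 24 h for the muscle, let-7, p53-induced, miR-29, blood-cell and mTOR-targeting lists, against DMSO in the resistant line for let-7, p53-induced, miR-181 and Sfmbt2, and against 24 h for miR-15/16, epithelial, Dlk1-Dio3, pluripotency-linked and Sfmbt2.

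A hypothesis was that miRNAs lying within 10 kb of each other share their change. In the resistant line against DMSO, 98.05% of 10000 random re-pairings of 179 probes had a larger mean difference than the 435 real pairs, 0.384 against 0.296 (permutation p = 0.0196). Without the 3 miR-17 clusters 83.65% did (permutation p = 0.164), so over all probes those clusters may carry the result. Among pairs above the negative controls the permutation p was 1e-04 for 124 pairs, the smallest possible, and 0.0196 for the 109 outside those clusters. Between both rapamycin groups the permutation p was 0.112 over all pairs, 0.0009 for the 124 pairs above the negative controls and 0.228 for the 109 outside those clusters. After 24 h it was 0.313 over all pairs and 0.350 and 0.530 for those sets.

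miR-805 and miR-689 had no locus of that name in the mouse gene table used here, so no position is given for them. Other named miRNAs, such as miR-21 and miR-146a, found no match either. Loci were matched by the array's name alone, so a gene listed under another symbol was missed. A missing match is therefore no sign that a miRNA has no locus. Where the signal of the miR-805 and miR-689 probes comes from was not tested. Across probes left out of the comparisons, limma, adjusted over all of these together, called 46, 173 and 234 of those not designed for mouse, 1, 11 and 13 miRPlus and 4, 13 and 17 obsolete probes, in the order 24 h against DMSO, resistant against DMSO and resistant against 24 h.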
